A study of Mus musculus with 12 samples.

How the data were processed

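Gene expression was measured in the prefrontal cortex and the whole striatum of outbred male Swiss mice that had drunk ethanol by free choice, with 3 arrays for each of 4 groups (inflexible and light drinkers in each region). Total RNA was extracted with TRIzol per the labels' protocols, and the biotin-labelled material was hybridised to 1-colour oligonucleotide arrays. The labels give 1 RNA pool concentration for each group. The 3 arrays of a group may therefore be hybridisations of a single pool, and every p-value here covers only the spread between arrays, not the spread between mice.

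The authors deposited 1 table of summarised probe set values, used here as log2 values. RMA, a procedure that corrects background, normalises and summarises the probes of a set, and the affy package are named in the submitters' processing notes without versions. The log base is not written in the table. It was read from the values, which ran from 2.76 to 11.56 on all 12 arrays with medians from 3.12 to 3.14, so fold changes assume base 2. Low values are compressed by this kind of summary, so the fold changes of weakly expressed genes are understated. The share of probe sets above a log2 value of 4 lay between 22.4% and 25.0% per array. The number of arrays limits the precision.

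All 45101 probe sets were read and 64 control probe sets were left out, which left 45037 for testing. No column of the table went unmapped. The platform annotation gave 34945 probe sets a single gene symbol, 932 several and 9160 none, and the gene ID of 34741 matched the RefSeq table, which changed 0 symbols. Probe sets with several or no symbols were tested and left unnamed. For 9010 of the 18193 genes more than 1 probe set was present, and the probe set with the highest mean over the 12 arrays represented the gene. Among the named genes that passed the test, 0 of 25 in prefrontal cortex and 1 of 4 in striatum (Arpp21) had another probe set above log2 4 with a difference of the opposite sign. Only 17 of the 25 and 2 of the 4 had more than 1 probe set, and some of these, such as Cabp7, had no other above log2 4. In striatum only Arpp21 could be checked in this way.

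The groups, the tests, the lists of genes, the rule for named genes and most alternative settings were chosen before the data were examined. A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 45037 probe sets, and a probe set was called at an adjusted p under 0.05. The contrasts were inflexible minus light drinkers in each region, the striatal minus the prefrontal difference, and striatum minus prefrontal cortex averaged over drinking class. No label states which test the authors used. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

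The 32 gene lists covered cell type markers of the dissected and neighbouring tissue, transmitter systems, stress and immune responses and basic cell functions, and 644 of their gene names were measured. At least 1 gene was shared with another list in 18 of them. Each list was compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists, and again with the correlation estimated for each list. The fry test was run as a further alternative. The camera test compares the mean of the list members' moderated statistics with that of all other genes and uses no ranks, so its direction can differ from the sign of its median or mean: this was so for the serotonin, noradrenaline and acetylcholine receptor list, the LRRK2 list, the astrocyte list and the oligodendrocyte precursor list in prefrontal cortex, and for the cortical excitatory neuron, oligodendrocyte precursor, choroid plexus and ependyma, opioid, interferon-stimulated, oxidative phosphorylation, cytosolic ribosomal protein and toll-like receptor lists in striatum, none of which was called.

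Named genes were, for each region, the 12 with the largest rise and the 12 with the largest fall among called genes whose 3 arrays of one class all lay above the 3 of the other. Where fewer passed, the remaining places were filled by the smallest unadjusted p and only values are given. For the difference between regions the 5 largest each way were named, for the region comparison the 6 largest each way, and from each list up to 4 members with the smallest p. Predicted and clone-named models were counted but not named. Lrrk2, Camk2a, Camk2n1, Pkp2 and Gabbr1 were named in any case. They were recalled from reports on this mouse model and may have been picked from these samples, so they are not independent evidence. Gabbr2 is not named in the probe table used here.

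A split between arrays was found in the control probe sets only after the data were seen. It was set at the widest gap in the mean of the hybridisation controls. No label gives a batch and the origin of the split is not known, so hybridisation batch is used here only as a name for it. The mean of 7 spiked bacterial hybridisation controls lay between 7.73 and 8.82 on 5 arrays and between 5.62 and 6.24 on the other 7, and the 18S ribosomal RNA probe sets ran the other way (5.57 to 7.63 against 8.54 to 9.02). In prefrontal cortex 1 array of each class had high controls (replicate 2 of both). In striatum 2 of 3 inflexible arrays (replicates 1 and 3) and 1 of 3 light arrays (replicate 1) did. The model was refitted with this split as a block, on the 7 arrays with low controls alone, and with a separate mean per group and batch for contrasts within each batch. These fits were added after the data were seen. Where a batch held a single array of a group, that array was assumed to vary like the others.

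Replicate numbers were checked for pairing by correlating, over the 10852 probe sets with a mean above 4, each array's deviation from its group mean. Arrays of the same number correlated at 0.741, 0.849 and 0.622 in prefrontal cortex, which passes the rule set for pairing (every pair over 0.1). Any pairing there would come from the data alone. Replicate 2 was the array with high controls in both classes, so the split in controls alone makes deviations of same-numbered arrays alike, and the rule could hardly fail. Inflexible replicate 1 correlated more with light replicate 3 (0.796). Inflexible replicate 3 correlated as much with light replicate 1 as with light replicate 3 (0.622 each). Pairing by number was thus not shown in prefrontal cortex. In striatum the same-number correlations were 0.250, 0.262 and -0.637, so numbers did not pair those arrays. The replicate block among the alternatives was fitted in both regions all the same.

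The other alternatives were a fit on the arrays of the region alone, the replicate number as a block, quantile normalisation, median centring, a filter on low values, an intensity trend with a robust prior, array weights, a minimum fold change of 1.5, the mean of a gene's probe sets, and leaving out each array in turn. The scripts were tested on simulated values of 45037 probe sets with independent noise. Known changes of 1.5-, 2- and 4-fold were set in 67, 67 and 66 of them. All of these had a mean above log2 4, so the shares recovered do not cover dimmer probe sets. In simulated prefrontal cortex 32.8% of changes of 1.5-fold, 59.7% of 2-fold and 98.5% of 4-fold were recovered with 3 false calls, and in simulated striatum 26.9%, 61.2% and 98.5% with 0 false calls. With the hybridisation block these shares were 64.2%, 89.6% and 100% in prefrontal cortex and 59.7%, 83.6% and 100% in striatum, with 12 and 8 false calls. A list shifted by 0.5 was recovered in both regions, and in simulated striatum 2 lists that had not been shifted were called as well, without the block.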

Results

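The data came from a mouse model of ethanol drinking that does not bend to a bitter taste. Male Swiss mice, an outbred stock, had 3 bottles with 5% ethanol, 10% ethanol and water from 6 weeks of age. They passed through 10 weeks of acquisition, 2 weeks without ethanol, 2 weeks of renewed access and 2 weeks in which quinine at 0.005 g/L made the ethanol bitter, followed by 1 more week of free choice. Inflexible drinkers preferred ethanol throughout, also with quinine, and light drinkers preferred water. Per the labels, mean blood ethanol was 113 ± 11.3 mg/dL in inflexible and 48 ± 13.3 mg/dL in light drinkers, with the kind of error not stated. The labels give 16 weeks in all and an age of 22 weeks at the end of the experiment. The phases up to the quinine weeks fill that time, so the further week of free choice is not covered by it. Each class had 3 arrays of prefrontal cortex and 3 of striatum, 12 arrays in all, and 45037 probe sets were tested. All levels below are deposited log2 values, given as mean ± SD with n = 3 arrays unless stated, and differences are inflexible minus light drinkers ± SE.

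The arrays separated by the level of the control probe sets and by tissue. The first principal component took 41.2% of the variance over 10852 probe sets and ran with the spiked hybridisation controls, which were high on 5 arrays and low on 7. The second took 33.3%, with the striatal arrays at one end, the light prefrontal arrays at the other and the inflexible prefrontal arrays between them. Because of the first, each comparison was also fitted with this split in controls, named the hybridisation batch here, as a block. Its origin is not known.

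**Figure D1:**
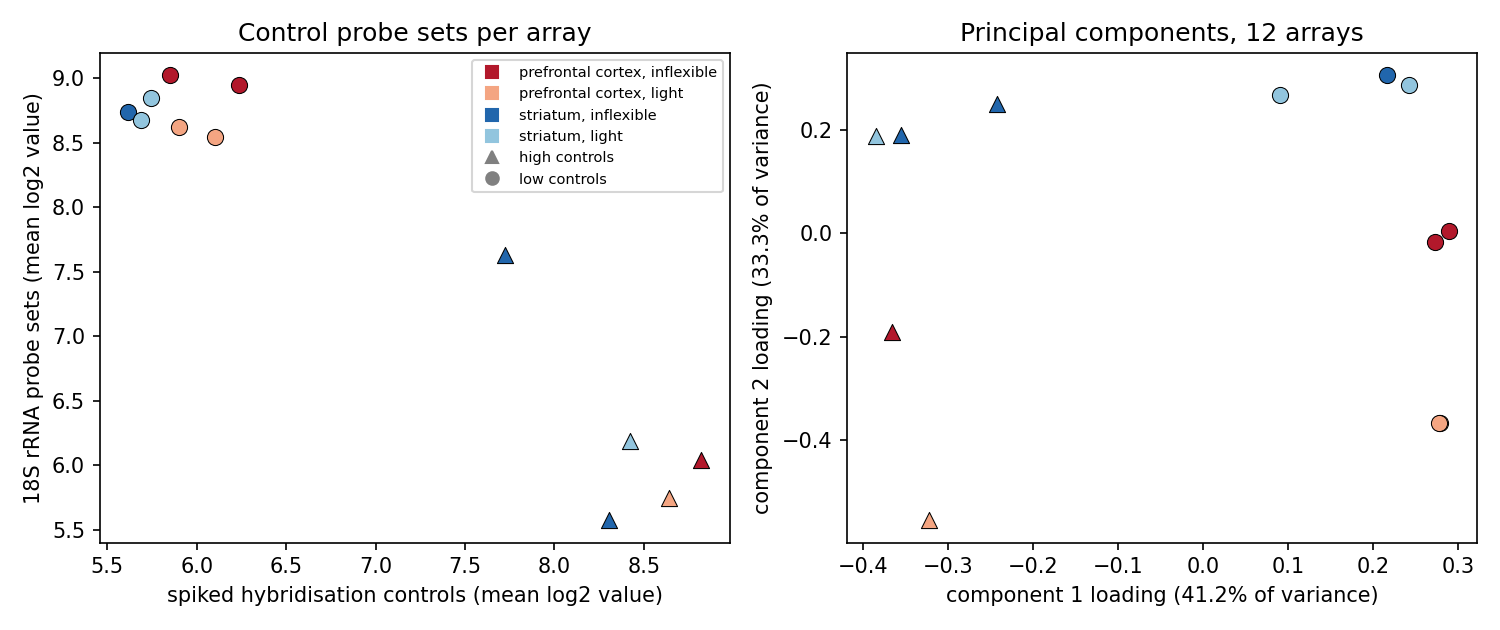
Left, mean log2 value of the spiked hybridisation controls (x axis) against that of the 18S ribosomal RNA probe sets (y axis), and right, loadings on principal components 1 and 2 (41.2% and 33.3% of variance), 1 point for each of the 12 arrays. Colours mark the 4 groups and triangles the 5 arrays with high controls, which lie at 7.73 to 8.82 on the control axis against 5.62 to 6.24 for the others.

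The prefrontal comparison asked which transcripts differed between mice that kept drinking ethanol despite quinine and mice that drank mostly water. Ttr, the thyroid hormone carrier secreted by the choroid plexus, stood at 10.78 ± 0.43 in inflexible and 4.53 ± 0.17 in light drinkers, a rise of 6.25 ± 0.23 or 76.1-fold. The calcium-binding protein gene Cabp7 rose by 2.16 ± 0.09 and the myelin protein gene Mobp by 2.03 ± 0.18. Genes of striatal projection neurons also rose, with the enkephalin precursor Penk up 3.00-fold (1.59 ± 0.13, from 5.37 ± 0.29 to 6.95 ± 0.09). Among falls, the activity-regulated gene Arc dropped by 1.05 (SE 0.13), from 5.96 ± 0.07 to 4.91 ± 0.10. At an adjusted p under 0.05 limma called 372 probe sets, 181 higher and 191 lower in inflexible drinkers, which covered 189 genes (105 higher, 84 lower). With the hybridisation batch as a block it called 1119.

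The other large rises were in Mal, a myelin proteolipid (2.82-fold, from 5.02 ± 0.06 to 6.51 ± 0.10), Pde10a, a phosphodiesterase abundant in striatal neurons (1.43 ± 0.17), Lpl, the enzyme lipoprotein lipase (1.42 ± 0.12), Spock3, a secreted proteoglycan (1.41 ± 0.22), and Shisa6, an AMPA receptor auxiliary protein (1.37 ± 0.07). Pcdh20, a protocadherin, rose by 1.28 ± 0.10, Nr3c2, the mineralocorticoid receptor, by 1.27 ± 0.07, and Drd1, the D1 dopamine receptor, by 1.25 ± 0.13. Adjusted p-values of these 12 genes lay between 3.9e-06 (Ttr) and 0.0218 (Spock3). Among the falls, Cdhr1, a cadherin known from photoreceptors and olfactory bulb neurons, changed by -1.11 ± 0.14. Below Arc in size came Jchain, the immunoglobulin joining chain (-0.95 ± 0.07), the zinc finger factor Hivep1 (-0.90 ± 0.12), the matrix proteoglycan Fmod (-0.89 ± 0.10) and the activity-regulated factor Egr2 (-0.88 ± 0.10). Stx1a, a syntaxin of the vesicle fusion machinery, changed by -0.84 ± 0.09, Pdzrn3, a ubiquitin ligase, by -0.82 ± 0.08, and Fabp7, a fatty acid-binding protein of glial progenitors, by -0.81 ± 0.10. Pitpnm3, of the phosphatidylinositol transfer family (-0.79 ± 0.09), Gng4, a G protein gamma subunit (-0.76 ± 0.09), and Slc6a20a, a proline transporter (-0.74 ± 0.10), completed the falls. The batch block left the differences of these 24 genes as they were, since each class had 1 array with high controls, and the adjusted p ran from 2.0e-09 (Ttr) to 0.0082 (Spock3). In each of these genes the 3 arrays of one class lay above all 3 of the other, which the naming rule required. Of all probe sets 12.9% did so, where chance gives 10%. Each of the 24 also differed in the same direction between light striatum and light prefrontal cortex (Stx1a 5.97 against 8.16). The light prefrontal arrays enter both comparisons, which favours this. Drinking class and tissue content were therefore not separated for these genes.

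**Figure D2:**
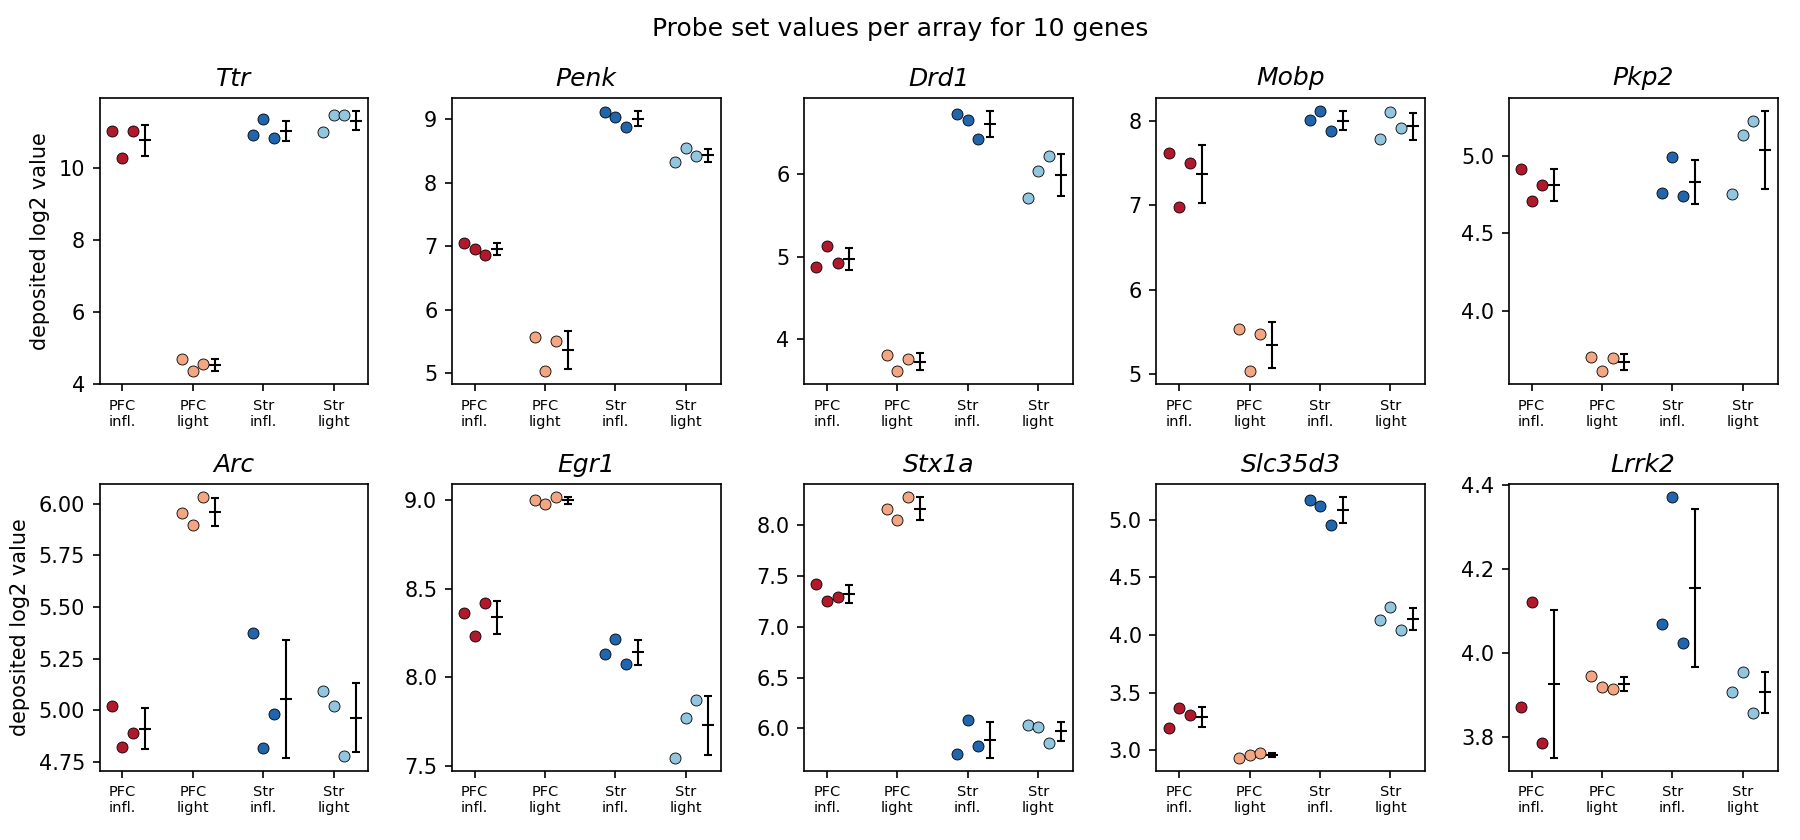
Deposited log2 values of 10 genes per array (points), with mean and SD (bars), for prefrontal cortex (PFC) and striatum (Str) of inflexible (infl.) and light drinkers, 3 arrays per group, each panel with its own y axis that does not start at 0. Ttr in light prefrontal cortex lies far below the other 3 groups (mean 4.53 against 10.78 to 11.33), and the 10 genes were picked among those of the naming rule after their values were seen.

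Markers of other cell types and of neighbouring tissue moved with drinking class in prefrontal cortex. The medium spiny neuron list, markers of the main striatal projection neuron, was higher in inflexible drinkers (median difference 0.71, adjusted p = 4.4e-24 by camera): 8 of 18 measured members rose, 0 fell, and 13 rose when adjusted over the list alone. Bcl11b, a transcription factor, rose by 1.04 ± 0.06 and Gpr6, an orphan receptor, by 1.13 ± 0.13, beside Penk and Drd1. In the oligodendrocyte and myelin list 6 of 17 rose and 0 fell (12 rose adjusted over the list alone, median 0.47, adjusted p = 4.5e-19), including Ermn (1.06 ± 0.13) and the myelin lipid enzyme Ugt8a (0.78 ± 0.10). Of the choroid plexus and ependyma list only Ttr passed over all genes, and 5 of 15 rose adjusted over the list alone (median 0.18, adjusted p = 9.2e-10). The dopamine signalling list was higher (median 0.16, adjusted p = 4.1e-04), and its 3 called members of 16, Drd1, Pde10a and Rgs9 (0.90 ± 0.12), a regulator of G protein signalling, are all in the medium spiny neuron list too. Adjusted over the list alone, 5 rose. On the low-control arrays alone the dopamine median was 0.09 (adjusted p = 0.0191). It was 0.08 with the mean of a gene's probe sets and 0.31 with the filter on low values. Without light replicate 2 it was 0.07 and without inflexible replicate 3 0.11. These 4 lists were also called with an estimated correlation and with the hybridisation batch as a block.

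In the same prefrontal samples the immediate early gene list, transcripts induced by neuronal activity, was lower in inflexible drinkers (median -0.25, adjusted p = 2.3e-09). Of its 24 members 5 fell and 0 rose, and adjusted over the list alone 9 fell and 1 rose. Egr1 changed by -0.66 ± 0.08 (from 9.00 ± 0.02 to 8.34 ± 0.10) and Trib1, a pseudokinase gene, by -0.30 ± 0.04, beside Arc and Egr2. The interneuron list was lower (2 of 20 fell, 3 adjusted over the list alone, median -0.13, adjusted p = 3.9e-04), through Dlx1, a homeobox gene (-0.35 ± 0.04), and the neuropeptide gene Npy (-0.59 ± 0.11). Its median was -0.06 without inflexible replicate 3 and -0.22 with the filter on low values. In the neuroblast and olfactory bulb list Cdhr1 fell and 4 of 12 fell adjusted over the list alone (median -0.12, adjusted p = 8.9e-05), and in the interferon-stimulated and MHC class I list H2-K1 fell (-0.58 ± 0.09), with 3 of 19 down adjusted over the list alone (median -0.03, adjusted p = 0.0017, and median -0.05 on the low-control arrays alone, without inflexible replicate 2 and without light replicate 1). These 4 lists were also called with an estimated correlation. With the batch block and an estimated correlation together, the interneuron list (adjusted p = 0.0715 with an estimated correlation) and the interferon list (adjusted p = 0.0806 with an estimated correlation) were not. Beside these falls the medium spiny neuron and myelin medians stood 0.71 and 0.47 higher.

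A further 7 prefrontal lists were called with the preset and not with an estimated correlation. With the batch block and an estimated correlation together, the microglia, vascular and glucocorticoid-responsive lists of these were called (each adjusted p = 0.0445), and fry called the glucocorticoid-responsive list (0.0398). The glucocorticoid-responsive list was higher (2 of 18 rose, 6 rose and 2 fell adjusted over the list alone, median 0.16, adjusted p = 0.0105), through Nr3c2 and the kinase Sgk1 (0.71 ± 0.11), with an adjusted p = 0.283 with an estimated correlation. The oxidative phosphorylation list was higher with 0 of 56 members called (1 rose adjusted over the list alone, median 0.13, adjusted p = 8.9e-05, and adjusted p = 0.468 with an estimated correlation). Microglial markers were lower (2 of 17 fell, also adjusted over the list alone, median -0.07, adjusted p = 0.0044), through Olfml3 (-0.31 ± 0.05) and the protease gene Ctss (-0.36 ± 0.07), with an adjusted p = 0.283 with an estimated correlation. Vascular cell markers were lower with 0 of 19 called (1 fell adjusted over the list alone, median -0.07, adjusted p = 0.0058, and adjusted p = 0.283 with an estimated correlation). The synaptic vesicle and release list was lower (Stx1a fell among 26, 1 rose and 1 fell adjusted over the list alone, median -0.13, adjusted p = 0.0105, and adjusted p = 0.158 with an estimated correlation). Chromatin regulators were lower with 0 of 27 called, also adjusted over the list alone (median -0.15, adjusted p = 0.0068, and adjusted p = 0.252 with an estimated correlation). Heat shock and unfolded protein genes were lower with 0 of 24 called (2 fell adjusted over the list alone, median -0.03, -0.05 on the low-control arrays alone, adjusted p = 0.0321, and adjusted p = 0.404 with an estimated correlation). Leaving out single arrays ended some of these calls: microglia without inflexible replicate 2 (adjusted p = 0.0862), vascular without that array, light replicate 1 or light replicate 3 (0.0571, 0.0534, 0.0727), and glucocorticoid-responsive without inflexible replicates 1 or 3 or light replicate 2 (0.0663, 0.0567, 0.0848). The same held for heat shock without inflexible replicate 2, light 1 or light 3 (0.217, 0.252, 0.117), oxidative phosphorylation without light 2 (0.174), and chromatin without inflexible 2 or light 1 (0.0783, 0.0558). Heat shock also lost its camera call with the filter on low values (0.0552) and the mean of a gene's probe sets (0.0821), and fry did not call it (0.315). The medians of several of these lists also rested on single arrays. That of microglia turned from -0.07 to 0.01 without inflexible replicate 2 and lay between -0.14 and -0.04 without any other prefrontal array. Oxidative phosphorylation went from 0.13 to 0.03 without light 2 and to 0.30 without inflexible 2. Heat shock went from -0.03 to -0.01 without light 1 and to -0.12 without light 2. The glucocorticoid-responsive median was 0.10 without inflexible 3 and 0.26 without inflexible 2. The chromatin median was -0.08 without inflexible 2 and the vascular median -0.11 without inflexible 3.

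The remaining 17 lists were not called in prefrontal cortex. Among the transmitter lists, the median was -0.12 for glutamate receptors and transport (0 of 29 called, adjusted p = 0.123), 0.03 for GABA receptors and synthesis (0 of 16, 0.209), 0.00 for endocannabinoid genes (0 of 10, 0.925) and -0.01 for serotonin, noradrenaline and acetylcholine receptors (0 of 23, 0.604). The opioid, CRF and stress neuropeptide list had members moving both ways (median 0.00, adjusted p = 0.821): Penk and the neuropeptide Y receptor gene Npy2r (0.90 ± 0.09) rose, and Crh, the corticotropin-releasing hormone gene (-0.73 ± 0.13), and Npy fell. Adjusted over each list alone, 1 rose and 4 fell among glutamate genes, 3 rose and 1 fell among GABA genes, and 3 rose and 4 fell in the opioid list. Of the cell type lists, cortical excitatory neuron markers had a median of -0.05 (adjusted p = 0.162), with Neurod6 risen (0.50 ± 0.09) and 1 up and 5 down adjusted over the list alone. That list was called with the replicate block (adjusted p = 0.0410), on the low-control arrays alone (0.0249) and without prefrontal inflexible replicate 2 (0.0240), an array without which the glutamate (0.0215) and ribosomal protein (0.0187) lists were called too. Medians were 0.00 for astrocytes (adjusted p = 0.985), 0.01 for oligodendrocyte precursors (0.821), -0.03 for blood cells (0.342) and 0.03 for neighbouring diencephalon and septum (0.286), each with 0 called over all genes. The LRRK2 and Parkinson-linked list (median 0.04, adjusted p = 0.966), ethanol and acetaldehyde metabolism (0.03, 0.249), toll-like receptors and cytokines (0.00, 0.966), cytosolic ribosomal proteins (0.02, 0.939) and voltage-gated and potassium channels (-0.04, 0.824) also had 0 called. In the circadian clock list (median -0.03, adjusted p = 0.0541) the repressor gene Bhlhe40 fell (-0.52 ± 0.07), and 3 fell adjusted over the list alone. The clock list was called with quantile normalisation (0.0407) and without striatal inflexible 2, inflexible 3, light 1 or light 3 (0.0355, 0.0392, 0.0405, 0.0442).

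**Figure D3:**
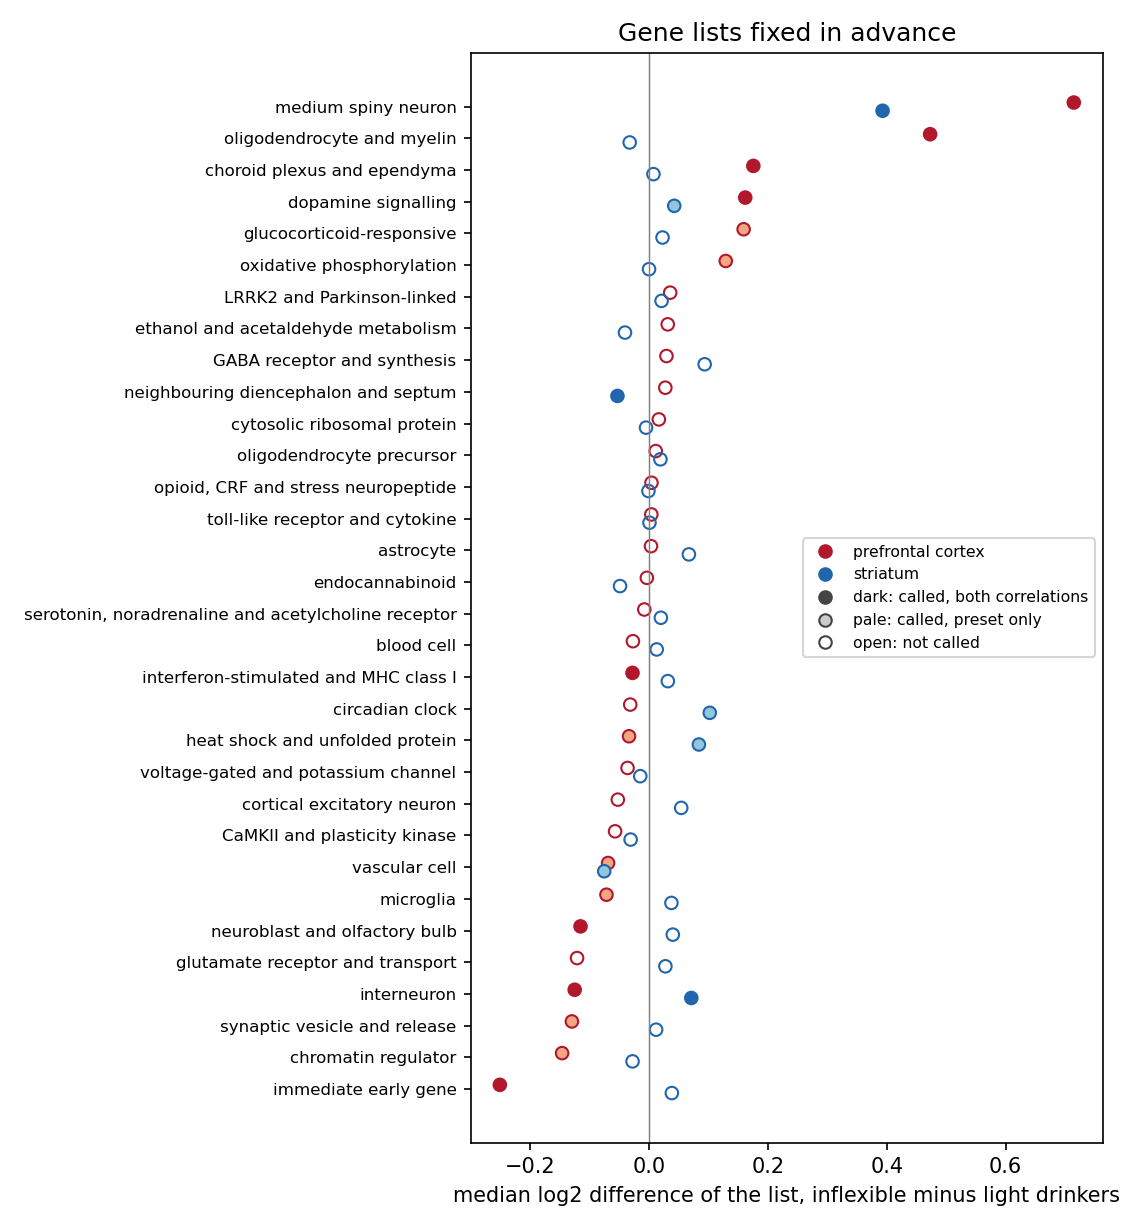
Median log2 difference, inflexible minus light drinkers, of the representative probe sets of each of 32 gene lists in prefrontal cortex and striatum, with dark points called by camera with both the preset and an estimated correlation (8 and 3 lists), pale points with the preset correlation alone, and open points not called. The medium spiny neuron list has the highest median in both regions, 0.71 and 0.39.

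Genes linked to this mouse model in earlier reports were followed in any case. In the CaMKII and plasticity kinase list (median -0.06, adjusted p = 0.866, 1 of 19 called, 2 rose and 2 fell adjusted over the list alone), Pkp2, which encodes the desmosomal protein plakophilin 2, rose in prefrontal cortex by 1.14 ± 0.12 (adjusted p = 0.0021), from 3.67 ± 0.05 to 4.81 ± 0.10. Camk2a, a CaMKII subunit (-0.31 ± 0.19, adjusted p = 0.883), and the CaMKII inhibitor gene Camk2n1 (-0.24 ± 0.08, adjusted p = 0.368) did not pass, nor did Lrrk2, a kinase gene linked to Parkinson disease (0.00 ± 0.10), or the GABA-B receptor gene Gabbr1 (0.01 ± 0.16). A second, dim Camk2n1 probe set (mean 3.97) fell by 2.09 (adjusted p = 7.2e-05), a value singled out after it was seen. In striatum none of these 5 genes passed: the differences were 0.25 ± 0.10 for Lrrk2, -0.29 ± 0.19 for Camk2a, 0.11 ± 0.08 for Camk2n1, -0.21 ± 0.12 for Pkp2 and -0.01 ± 0.16 for Gabbr1, each with an adjusted p of 1.00.

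The prefrontal call count was 649 within the low-control arrays and 1831 within the high-control arrays, where each class had 1 array. It fell to 193, 227 and 171 without inflexible replicates 1, 2 and 3, to 157 and 175 without light replicates 1 and 3, to 198 in a fit of the prefrontal arrays alone and to 169 with a minimum fold of 1.5, and reached 2955 with array weights. Spock3 was no longer called without any 1 of the 6 prefrontal arrays (adjusted p from 0.0527 to 0.103), Hivep1 without light replicate 1 (0.0503) and Slc6a20a without inflexible replicate 3 (0.0545). With the replicate block Pde10a (adjusted p = 0.0598), Spock3 (0.135), Egr2 (0.0505), Pitpnm3 (0.0563) and Gng4 (0.0518) lost their calls, and with the prefrontal arrays alone Cdhr1 (0.10), Fmod (0.0775), Egr2 (0.0585) and Slc6a20a (0.0519) did. Within the high-control arrays Spock3 (1.43 ± 0.37, adjusted p = 0.0974), Arc (-1.07 ± 0.20, 0.0519), Hivep1 (-0.94 ± 0.24, 0.0894), Egr2 (-0.65 ± 0.17, 0.0902) and Pitpnm3 (-0.63 ± 0.12, 0.0552) were not called, nor were Spock3 (1.40 ± 0.27, 0.0860) and Hivep1 (-0.88 ± 0.17, 0.0875) within the low-control arrays. The SE of each was larger than over all arrays. The differences of Spock3, Arc and Hivep1 stayed near those over all arrays.

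The striatal comparison asked the same question of the whole striatum. Slc35d3, a nucleotide sugar transporter family member known from striatal neurons, rose by 0.94 ± 0.07, from 4.14 ± 0.10 to 5.08 ± 0.11 (1.92-fold, adjusted p = 0.0025). Kcna5, a voltage-gated potassium channel gene, rose by 0.65 ± 0.07, Arpp21, a cyclic AMP-regulated phosphoprotein gene of striatal neurons, by 0.53 ± 0.05, and Kazn, a gene of the desmosome-linked protein kazrin, by 0.52 ± 0.05, each with an adjusted p of 0.0240. In all 4 genes every inflexible array lay above every light array, which the naming rule required. These were the only named genes among 5 called probe sets (4 higher, 1 lower). Of the 45037 probe sets, 1588 had an unadjusted limma p under 0.05, a smaller share than the 0.05 that chance gives. The classes did not overlap in 7.84%, where chance gives 10%. The other Arpp21 probe sets differed by -0.33, -0.21, -0.08 and 0.38. Over the alternatives the adjusted p ran from 0.0027 to 0.285 for Slc35d3, 4.2e-04 to 0.629 for Kcna5, 0.0080 to 0.598 for Arpp21 and 0.0084 to 0.325 for Kazn.

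The other striatal genes with the smallest p-values did not pass. Slc8a1, a sodium-calcium exchanger gene, differed by -1.23 ± 0.16 (adjusted p = 0.0848), Ptgds, a prostaglandin D synthase abundant in meninges, by -1.26 ± 0.21 (0.219), Gad2, a GABA-synthesising enzyme gene, by 0.81 ± 0.13 (0.193), and Mgp, a matrix protein gene, by -0.67 ± 0.11 (0.193). The differences were 0.37 ± 0.04 for Pdzd2, -0.45 ± 0.06 for Washc2, -0.42 ± 0.06 for the matrix gene Dcn, -0.51 ± 0.07 for Shisa6, -0.38 ± 0.06 for Tbc1d24, 0.42 ± 0.06 for Rgs20 and -0.47 ± 0.07 for Nr3c2. For Iqgap2 it was -0.51 ± 0.08, for Dmkn 0.62 ± 0.10, for the retinoic acid receptor gene Rarb 0.52 ± 0.09, for the cortical and hippocampal factor Neurod6 -0.51 ± 0.09, and for Rem2 0.54 ± 0.09. Inhba, an activin subunit gene, differed by 0.29 ± 0.05, Akr1e1 by -0.20 ± 0.03, Adamts3 by 0.36 ± 0.06 and Htr5b by -0.25 ± 0.05. Adjusted p-values of the 20 ranged from 0.0523 to 0.251. Array weights brought calls for Slc8a1 (0.0085) and Rarb (0.0153), an intensity trend for Slc8a1 (0.0327) and quantile normalisation for Inhba (0.0404). Leaving out 1 array brought calls for Slc8a1 (0.0019 without striatal light 1), Pdzd2 (0.0229 without prefrontal light 1), Rarb (0.0339 without prefrontal light 2) and Washc2 (0.0488 without striatal light 2), and the batch block for Pdzd2, Washc2, Mgp, Dmkn and Inhba (from 0.0186 to 0.0439).

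No member of the 32 lists passed over all genes in striatum, but 7 lists were called as sets. Medium spiny neuron markers were higher in inflexible drinkers (median 0.39, adjusted p = 3.1e-14), with 8 of 18 up adjusted over the list alone. Drd1 stood at 6.61 ± 0.16 against 5.99 ± 0.26 and Penk at 9.01 ± 0.12 against 8.43 ± 0.10. Interneuron markers were higher (median 0.07, adjusted p = 0.0012, 3 of 20 up adjusted over the list alone), and the list of neighbouring diencephalon and septum was lower (median -0.05, adjusted p = 8.7e-04, 1 of 14 down adjusted over the list alone), with the septal and thalamic factor Zic1 at 5.42 against 6.15. These 3 were also called with an estimated correlation. The vascular list was lower (median -0.08, adjusted p = 1.4e-04, 1 of 19 down adjusted over the list alone, adjusted p = 0.170 with an estimated correlation), and the dopamine signalling list higher (median 0.04, adjusted p = 0.0041, 1 of 16 up adjusted over the list alone, adjusted p = 0.0552 with an estimated correlation). Heat shock genes were higher (median 0.08, adjusted p = 0.0041, 1 of 24 up adjusted over the list alone, adjusted p = 0.406 with an estimated correlation), as were circadian clock genes (median 0.10, adjusted p = 0.0298, 0 of 19 adjusted over the list alone, adjusted p = 0.138 with an estimated correlation). The other 25 lists were not called, with medians from -0.05 to 0.09 and a lowest adjusted p of 0.0847. The immediate early gene median was 0.04 (adjusted p = 0.607). Drinking class was not separated from the tissue content of the dissected striatum for these lists. The same limit holds for the called genes Slc35d3, Kcna5, Arpp21 and Kazn, each higher in light striatum than in light prefrontal cortex.

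The hybridisation batch was uneven between the striatal classes. With it as a block, 34 probe sets were called (21 higher, 13 lower), all 4 genes passed (adjusted p from 0.0075 to 0.0246), the dopamine list did not (0.0554), and the interneuron list had an adjusted p = 0.152 with an estimated correlation. Within the low-control arrays 0 were called and within the high-control arrays 6, with none of the 4 genes. Their differences within the low- and high-control arrays were 0.97 and 0.93 for Slc35d3 (SE 0.12 in each), 0.62 and 0.76 for Kcna5 (SE 0.10), 0.53 and 0.52 for Arpp21 (SE 0.087) and 0.47 and 0.52 for Kazn (SE 0.087). The calls ended with a larger SE on fewer arrays, not with a fall of the differences to near 0. On the low-control arrays alone the interneuron (median 0.04, adjusted p = 0.222) and dopamine (0.08, 0.211) lists were not called. The medium spiny neuron median was 0.35 with the block and 0.25 on the low-control arrays alone (adjusted p = 1.1e-09 and 3.0e-05). With the block the vascular median was -0.03 (0.0133) and the heat shock median 0.13 (2.2e-06, and adjusted p = 0.0157 with an estimated correlation), and the clock median was 0.06 on the low-control arrays alone (0.0122). The block added calls for astrocytes (median 0.10, adjusted p = 0.0430), microglia (0.10, 0.0133), oxidative phosphorylation (0.10, 1.6e-05) and ribosomal proteins (0.10, 0.0010). These had adjusted p = 0.451, 0.133, 0.360 and 0.384 with an estimated correlation. Without single striatal arrays the vascular median ran from -0.12 to -0.04. The heat shock median was 0.05 without inflexible 2. The clock median was 0.06 and the diencephalon and septum median -0.03 without inflexible 3. The dopamine median was 0.27 with the filter on low values and the clock median 0.03 with the mean of a gene's probe sets. The count was 1 with striatal arrays alone and 0 with the replicate block, whose numbers did not pair the striatal arrays. It was 2 without any of striatal inflexible replicates 1, 2 and 3, striatal light 3, prefrontal inflexible 2 or prefrontal light 3, 3 without prefrontal inflexible 1 or striatal light 1, and 9 without prefrontal light 2. Heat shock lost its call without striatal inflexible 2 or light 1 (0.227, 0.20), and the clock list without inflexible 2, inflexible 3 or light 1 (0.239, 0.141, 0.246). Calls were gained by the GABA list with the replicate block (0.0080), the filter on low values (0.0269) and without striatal light 2 (0.0295), and by oxidative phosphorylation without striatal inflexible 3 (0.0080).

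Whether the difference between the drinking classes was itself different in the 2 regions was tested as the striatal minus the prefrontal difference, and 141 probe sets passed (52 higher, 89 lower). Ttr had the largest value, -6.54 ± 0.32: it rose in prefrontal cortex and stood at 11.04 ± 0.28 against 11.33 ± 0.27 in striatum. Cabp7 (-2.35 ± 0.13), Mobp (-1.96 ± 0.25), Shisa6 (-1.88 ± 0.10) and Nr3c2 (-1.74 ± 0.10) followed. On the positive side were the activity-regulated genes Arc (1.14 ± 0.19), Egr1 (1.07 ± 0.11) and Egr2 (0.94 ± 0.15), the homeobox gene Meis2 (1.07 ± 0.16) and Pitpnm3 (1.01 ± 0.13). Beside them the medium spiny neuron, myelin and choroid plexus medians differed between regions by -0.27, -0.70 and -0.16.

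With the hybridisation batch as a block 443 probe sets passed and all 10 genes kept their call, and within the low- and high-control arrays 70 and 649 passed. The replicate block left 69 and ended the calls of Arc (adjusted p = 0.0671), Meis2 (0.109), Pitpnm3 (0.119) and Egr2 (0.156), and 87, 76, 75, 62, 91, 79, 86 and 88 passed without prefrontal inflexible 1 or 3, prefrontal light 1 or 3, striatal inflexible 1 or 3, or striatal light 2 or 3. Arc was called without striatal inflexible 1 or 2 and lost its call without any other array (adjusted p from 0.0642 to 0.139). Within the low-control arrays the calls ended for Arc (0.96 ± 0.23, adjusted p = 0.272), Meis2 (0.90 ± 0.15, 0.121), Pitpnm3 (0.92 ± 0.14, 0.0994) and Egr2 (1.14 ± 0.18, 0.122). Within the high-control arrays they ended for Arc (1.15 ± 0.27, 0.0940), Pitpnm3 (1.04 ± 0.16, 0.0517) and Egr2 (0.56 ± 0.22, 0.229). Quantile normalisation ended the calls of Arc (0.0610) and Meis2 (0.0567), median centring that of Arc (0.0509) and an intensity trend that of Meis2 (0.0535). Meis2 also lost its call without prefrontal inflexible 1, 2 or 3, prefrontal light 1, striatal inflexible 1 or 3, or striatal light 2 or 3 (from 0.0673 to 0.0943), and Egr2 without prefrontal inflexible 2 or 3, prefrontal light 1 or 3, any striatal inflexible array, or striatal light 2 or 3 (from 0.0581 to 0.121). Single arrays further ended calls of Mobp (0.0524 and 0.0503 without inflexible replicate 3 of prefrontal cortex or of striatum) and Pitpnm3 (0.0516 without prefrontal light 3).

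The region comparison checked the labels and the dissection against known markers. Penk was higher in striatum by 2.56 ± 0.09 (5.88-fold), as were Ppp1r1b, the dopamine-regulated phosphoprotein DARPP-32 (2.31 ± 0.22), Gng7, a striatal G protein gamma subunit (2.14 ± 0.19), Gpr6 (2.14 ± 0.09), Pde10a (2.05 ± 0.12) and Rasd2, the striatal small GTPase Rhes (1.96 ± 0.12). Lower in striatum were Cux2, a factor of upper cortical layers (-1.97 ± 0.13), the interneuron peptide gene Vip (-1.95 ± 0.10), the neuronal factor Mef2c (-1.84 ± 0.14), Stx1a (-1.82 ± 0.07), Car10 (-1.80 ± 0.17) and Ptgds (-1.62 ± 0.15). In the medium spiny neuron list 17 of 18 members were higher in striatum (18 adjusted over the list alone), and in the cortical excitatory neuron list 8 of 18 were lower and 3 higher (9 and 3 adjusted over the list alone). The myelin list was higher in striatum (13 of 17, median 0.76, adjusted p = 1.1e-20), as were the choroid plexus (9 of 15, 0.24, 1.4e-13) and dopamine lists (7 of 16, 0.09, 2.3e-06), while the immediate early gene (-0.19, 6.8e-07) and circadian clock (-0.13, 5.9e-04) lists were lower. GABA (median 0.13), CaMKII (-0.10), heat shock (-0.07), ribosomal (0.12) and synaptic vesicle (-0.06) lists had adjusted p = 0.0789, 0.0635, 0.379, 0.573 and 0.153 with an estimated correlation and were called with the preset value, and 20 lists were not called. In the blocked fit the medians of the cortical excitatory and synaptic vesicle lists were -0.28 and -0.11, against -0.15 and -0.06 without it. In all, 1720 probe sets differed, 735 higher and 985 lower in striatum, and with the batch block 3601 did.

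Across 18193 genes the differences in the 2 regions had a Pearson r of -0.0914, a description only since genes are not independent replicates. With the batch block it was -0.0172, on the low-control arrays alone 0.130, and without single arrays it ran from -0.241 (without prefrontal inflexible 2) to 0.0630 (without prefrontal light 2). No gene was called in both regions, where independent lists would share 0.0231 risen genes. With the batch block 2 genes rose in both and 1 fell in both (0.266 and 0.0611 for independent lists), while 1 rose in prefrontal cortex and fell in striatum and 3 did the reverse (0.0664 and 0.244).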

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

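The tests of the hybridisation batch, of dilution and of striatal tissue alone were chosen after the result each measures had been seen, as were the batch-blocked and within-batch fits.

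The difference between inflexible and light drinkers was not the same in the 2 regions for 141 probe sets, by the test of the difference itself. That test does not separate drinking class from tissue content. Of the 100 splits drawn, 3 gave as many, the real one included, a share under 0.05. It bears on chance among the arrays and not between animals, since each group may be 1 pool. The share rests on 1 probe set, since 2 further splits gave 140, one of them with the striatal classes exchanged and the prefrontal classes kept. The highest other count was 1684, several times the real one, from a split that set the high-control prefrontal arrays with the low-control striatal ones, and 431 came from one with the 3 high-control striatal arrays together. Both follow the hybridisation batch and point to a structure of the arrays, but the one with 431 also kept the real prefrontal classes. Apart from the real one, the other splits that kept these classes gave 36 to 140, and those that mixed them 0 to 2 but for the 1684, so the count follows the prefrontal difference as well as the batch. With the batch as a block 443 passed, and within the low- and high-control arrays 70 and 649.

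The striatal minus prefrontal difference was 1.14 for Arc, 1.07 for Egr1, 1.07 for Meis2, 1.01 for Pitpnm3 and 0.94 for Egr2. It was -6.54 for Ttr, -2.35 for Cabp7, -1.96 for Mobp, -1.88 for Shisa6 and -1.74 for Nr3c2. Among the lists, the median was -0.27 for medium spiny neurons, 0.24 for interneurons, -0.70 for myelin, -0.16 for choroid plexus, 0.18 for neuroblasts and olfactory bulb, -0.066 for diencephalon and septum, 0.27 for immediate early genes, 0.068 for interferon-stimulated genes and 0.11 for the circadian clock, each called by camera with the preset and the estimated correlation. With the batch block and an estimated correlation together, choroid plexus and interferon-stimulated genes were not called (adjusted p = 0.109 with an estimated correlation for each). The medians of 0.14 for microglia, 0.18 for heat shock, -0.14 for oxidative phosphorylation and 0.17 for synaptic vesicles were called with the preset value but not, without the block, with an estimated one (adjusted p = 0.25, 0.203, 0.703 and 0.175 with an estimated correlation). With the block, microglia (median 0.23) and heat shock were called at an estimated correlation (adjusted p = 0.0205 and 0.0157 with an estimated correlation), and oxidative phosphorylation lost its call at the preset one (median -0.02, adjusted p = 0.201).

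Striatal and myelin genes were higher in the inflexible prefrontal cortex, as was the choroid plexus gene Ttr, while the rest of the choroid plexus list lay near background. The hybridisation batch was balanced between the prefrontal classes, so a batch shift common to both classes cancels by design. The medium spiny neuron median was 0.71 within the low-control arrays and 0.88 within the high-control ones (1 array per class). The difference was thus not confined to 1 batch. Tissue next to the prefrontal cortex in the dissected sample stays open. Of 46 genes higher in light striatum than in inflexible prefrontal cortex, 97.8% were also higher in inflexible than light prefrontal cortex. Of 72 lower ones 98.6% were lower. The inflexible prefrontal arrays enter both comparisons with opposite sign, so noise alone would work against such agreement. Striatal tissue alone was argued against for the myelin genes, whose implied share of striatal RNA had a lower quartile of 45.6% against an upper quartile of 33.7% for medium spiny neuron genes, so another source such as white matter may add to it. A difference from drinking class itself was not tested apart from tissue content and stays open, since each group may be 1 pool.

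Immediate early genes were lower in the inflexible prefrontal cortex. The balanced batch cancels here by design as well. Over the 14 members above log2 4 the median was -0.28 within the low-control and -0.33 within the high-control arrays, so the fall was not confined to 1 batch. Dilution by neighbouring tissue could account for part of the fall: a mix at the share set by medium spiny neuron genes predicted a median of -0.15 against -0.29 observed, and the median of observed minus predicted was -0.15, between the bounds set for and against it. Of the 14 members 10 lay lower than predicted, furthest Arc (-1.05 against -0.23 predicted), Egr2 (-0.88 against -0.24), Egr3 (-0.70 against -0.21) and Egr1 (-0.66 against -0.27), and Arc at 4.91 ± 0.10 was no higher than in light striatum (4.96 ± 0.17), so a striatal mix at that share does not reach these falls. These are the members with the largest gaps, and a mix with other tissue was not modelled, so dilution and a change with drinking class cannot be told apart for the list as a whole, and the latter was not tested.

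Pkp2, Cabp7, Shisa6 and Nr3c2 were low in the light prefrontal cortex and high in the other 3 groups. Striatal tissue alone stays open: the lowest share of striatal RNA the 4 genes implied was 53.0%, against an upper quartile of 33.7% from medium spiny neuron genes, but Cabp7, Shisa6 and Nr3c2 were picked for large rises in prefrontal cortex, which makes their shares high. Pkp2 was named beforehand and implied the highest share, 76.4%, but it was recalled from reports that may rest on these samples and lay at 3.67 in light prefrontal cortex, so 1 dim gene does not decide it. Hippocampal tissue in 3 of the 4 groups may contribute but stays undecided. Of 9 hippocampal markers above log2 4 in any group, 8 were higher in the mean of these 3 groups than in light prefrontal cortex. Zbtb20 was higher by 1.43, but Wfs1, Bok and Stxbp6 by only 0.07, 0.12 and 0.05. The median was 0.39, between the bounds set, and 6 of the 9 were above log2 4 in light prefrontal cortex too. Prox1, Dsp and Spink8, higher by 0.90, 1.28 and 1.10, were not. They were kept only through groups where they were high, which raises both the median and the count of 8. Among the 6, Rgs14 differed by 0.39 and Nectin3 by -0.34, beside Zbtb20, Wfs1, Bok and Stxbp6. The markers therefore cannot decide it. A difference with drinking class was not tested apart from tissue content and stays open.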

How the results depend on the processing

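The batch-blocked, low-control and within-batch fits were chosen after the data were seen. Of the comparisons of named genes with an alternative, 1556 kept direction and side of the threshold, 128 lost a call, 13 gained one and 17 changed sign. None of those 17 was a called gene. The 1556 include genes not called in the main fit, which had no call to lose, and fits that leave a difference unchanged by design. They therefore overstate how stable the called genes were. The cause was not tested for the changes below. In prefrontal cortex (372 probe sets) the count was 198 with its own arrays alone, 2955 with array weights, 169 with a minimum fold of 1.5, 1119 with the batch block, 1243 on low-control arrays alone, and 649 and 1831 within low- and high-control arrays. In striatum (5) it was 1 with its own arrays, 3 with the minimum fold, 34 with the batch block, and 0 on and within the low-control arrays. Quantile normalisation gave 7, of which 4 were higher. For the difference between regions (141) it was 88 with an intensity trend, 800 with array weights, 443 with the batch block, and 70 and 649 within low- and high-control arrays. For the region comparison (1720) it was 4136 with array weights, 499 with the minimum fold, 3601 with the batch block and 3246 on low-control arrays. Array weights were lowest for replicate 2 of both prefrontal classes (0.257 inflexible, 0.221 light).

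Prefrontal lists (15 called) numbered 8 with an estimated correlation and 9 with it and the batch block, and striatal lists (7) numbered 3 and 3, and 4 with fry. The replicate block was fitted in both regions, although pairing by replicate number was not shown in either. With it 295 prefrontal, 0 striatal, 69 between-region and 2076 region probe sets were called. The correlation of the changes changed sign on the low-control arrays (0.130). Lrrk2 in prefrontal cortex was -0.10 with array weights and -0.10 on and within the low-control arrays. Gabbr1 there was -0.074 with array weights and -0.061 on and within the low-control arrays, and in striatum 0.085 with the batch block and 0.18 within the high-control arrays. Leaving out 1 array at a time gave 157 to 394 probe sets in prefrontal cortex, 2 to 9 in striatum, 62 to 161 between regions and 1286 to 1826 for region, 12 to 16 and 5 to 8 lists, a correlation from -0.241 to 0.0630, Lrrk2 from -0.10 to 0.071, and Gabbr1 from -0.13 to 0.10 in prefrontal cortex and -0.12 to 0.14 in striatum. Signal over background limits what can be seen, as most probe sets lay below log2 4 on every array.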

Other observations

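The batch-blocked fit reported here was chosen after the data were seen, and the split tests before.

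With the hybridisation batch as a block, further striatal genes passed that had not done so without it, and they were chosen here after their values were seen. Rbp4, a retinol carrier, was higher in inflexible drinkers by 0.61 ± 0.06 (adjusted p = 0.0186), Lamp5, a neuronal membrane protein gene, by 0.80 ± 0.11 (0.0498), and Pdyn, the dynorphin precursor, by 0.28 ± 0.04 (0.0498). Egr1 was higher by 0.46 ± 0.05 (0.0317) in striatum, while in prefrontal cortex it was lower by the same fit (-0.66, 3.6e-04). Tfrc, the transferrin receptor, was lower (-0.43 ± 0.05, 0.0445), as was the protocadherin gene Pcdh19 (-0.34 ± 0.04, 0.0477).

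The 3 against 3 design of each region gives 10 splits, too few for a share under 0.05. In prefrontal cortex 1 of 10 splits, the real one, gave 372 probe sets, and the highest other gave 0. In striatum 2 of 10 gave as many as the real 5, and the highest other, 47, came from the split that put the 3 high-control arrays together. With the batch as a block 34 were called, and 0 and 6 within the low- and high-control arrays. For the region comparison 1 of 100 drawn splits, the real one with 1720, gave as many, the highest other being 752. Not every possible split was drawn, so this makes chance among the arrays unlikely for that count without excluding it. It does not bear on chance between animals, since each group may be 1 pool.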
